A study of Cricetulus griseus with 27 samples.

How the data were processed

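Small RNA was sequenced from CHO-K1 cells, an epithelial-like line of Chinese hamster ovary origin used to make recombinant proteins, and from 2 kinds of vesicle shed by them: microparticles (MPs), larger vesicles that bud from the plasma membrane, and exosomes, smaller vesicles released from endosomal compartments. Per the labels' protocols, shaken cultures of 15 mL with 6 mM glutamine were harvested on day 3 from a standard culture, an osmotic culture (60 mM NaCl added, raising osmolarity by 120 mOsm/L) and an ammonia culture (9 mM NH4Cl added). The 27 libraries form 9 groups of 3, fraction by culture, and the labels call the replicates biological. Total RNA was extracted with a miRNeasy micro kit, measured with a Qubit high sensitivity assay and sized on a Fragment Analyzer, per the labels' protocols. How cells, MPs and exosomes were separated is not given in the sources used here.

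The library chemistry changed with the culture. Per the labels' protocols, the 9 standard libraries were made with the NextFlex Combo-Seq kit, which captures mRNA and miRNA together, and formed 1 pool; the 18 stressed libraries were made with the TruSeq Small RNA kit and formed another. Stress against standard culture therefore cannot be told apart from the kit and the pool in any comparison that uses both. Read trimming and length limits, named below for the stressed libraries, may change with them. Fractions within a culture, and osmotic against ammonia culture, were compared inside 1 kit and 1 pool.

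FastQC 0.10.1, cutadapt 2.8 and the genome builds GRCm38, Rnor_6.0 and GRCh38 are named in the submitters' processing notes. The deposited count table gives whole-number read counts per mature miRNA entry, and per the file headers reads were grouped on the mature sequence and those of the stressed libraries were trimmed and limited in length. The counting tool is not given in the sources used here. The table has 4815 entries, each named by species: 351 for the Chinese hamster (cgr), 1776 for the mouse (mmu), 405 for the rat (rno) and 2283 for the human (hsa). At least 1 count was found for 924 of them. The same miRNA can appear under several species, and near-identical members of a family (the let-7 members above all) can share reads that the counting could split in any proportion, so values of single paralogs are uncertain. The deposited columns named CPM are a normalised signal that the authors made: each equals the count divided by an effective library size and scaled as CPM, tested on every value to a relative deviation of 7.43e-10, and their sums differ between libraries because the authors' scaling factors run from 0.0595 to 2.15. A table deposited by the authors gives 18 contrasts with log2 fold changes and false discovery rate p-values. It served for comparison only. The 54 columns of values per sample in that table were not used. CPM printed here is the count divided by the library's summed count, scaled in the same way.

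Totals ran from 26516 to 10374430 counts per library. A count of 0 allows up to 3 counts over a group's summed total. This floor was 6.47 CPM in standard cells, 0.918 in standard MPs, 0.401 in standard exosomes, 0.112 in osmotic cells, 1.22 in osmotic MPs, 12.7 in osmotic exosomes, 0.168 in ammonia cells, 0.400 in ammonia MPs and 6.32 in ammonia exosomes. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. A fold against a group with all libraries at 0 is given as a lower bound against that group's floor, and no fitted fold is printed for it. Such a bound holds for counting error only. In stressed MPs and exosomes abundant entries were at 0 in single libraries more often than read sampling gives, so true folds there can be smaller.

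Counts were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr by group) in R 4.3.3, with limma 3.58.1 for list tests. P-values were adjusted by the Benjamini-Hochberg method over the entries tested, and an entry passed at an adjusted p under 0.05. Printed adjusted p-values are from this test unless another is named. Log2 fold changes compare groups of 3 libraries and are given with an SE. The SE was derived from the test's F statistic, so it rests on the spread over all libraries of the fit. Fractions in standard culture were compared in a fit of the 9 standard libraries (351 entries tested, biological coefficient of variation 0.301). Fractions in stressed cultures and osmotic against ammonia culture came from a fit of the 18 stressed libraries (332 entries, 1.38), and stress against standard culture from a fit of all 27 (420 entries, 1.12). There were 18 comparisons of groups and 6 interactions, the latter testing whether the vesicle minus cell difference changed between cultures. The tests, the fits, the lists and the naming rule were chosen before the data were examined.

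By that rule, a comparison names entries that passed, averaged at least 50 CPM in either group and had no overlap between the libraries of the 2 groups: the 8 largest rises and the 8 largest falls, or fewer from the top in secondary comparisons, and 5 on each side for interactions. It also names the 10 most abundant entries of each standard fraction, the 5 most abundant of each stressed group, and from each list the 2 to 4 members with the largest absolute log2 fold change. A name that occurs under several species is given once.

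The 16 lists were the let-7 family; the miR-17~92 cluster with its paralogs; the miR-15/16, miR-30, miR-29, miR-10, miR-99, miR-100, miR-125 and miR-181 families; the miR-232724 clusters; miR-221 and miR-222; the miR-200 family; miRNAs linked to p53; miRNAs linked to hypoxia or cell stress; miRNAs proposed for CHO cell engineering; miRNAs often reported in extracellular vesicles; markers of other cell types; and database entries that overlap fragments of other RNA classes. Members were matched by exact name. Since hamster entries often carry no arm suffix, matching with the suffix left off is an alternative chosen after seeing the data; it raises the let-7 list from 5 to 9 members and is called the extended list. Lists with at least 3 tested members were tested against the other entries with camera at its preset inter-gene correlation of 0.01. They were then tested with an estimated correlation and with fry, which asks only whether a list's members move one way. P-values were adjusted over the lists within each comparison, not over all 225 list tests. Of the 14 camera calls, 3 held with an estimated correlation; fry called 116. Shares of counts use the extended lists.

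The edgeR test was run on simulated data drawn from the libraries' own means and totals, with 200 entries changed, for 4 comparisons of groups. Interactions were not simulated. For standard exosomes against cells it recovered 46.8% of 2-fold, 86.2% of 4-fold and 100% of 16-fold changes, with 5.66% false calls. For osmotic MPs against cells it recovered 1.64% of 16-fold changes, and for osmotic against ammonia cells 0% of them, although a fit of those 6 cell libraries alone recovered 65.6%. For osmotic against standard MPs it recovered 7.69% of 16-fold and 0% of 2-fold and 4-fold changes, with 16.7% false calls. Each comparison was simulated once. The 16.7% rests on few simulated calls, so it does not estimate the share of false calls among the real ones.

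The alternatives were RLE scaling, library size only, DESeq2 1.42.0, no filter on low counts, a replicate block, counts summed over species names, a fit of the compared groups alone, and leaving out each library in turn. Alternatives chosen after seeing the data were the authors' effective library sizes, leaving out the 6 stressed exosome libraries, hamster-named entries alone, and the extended lists. Overlaps of comparisons that share their standard libraries were set beside 30 simulations of unchanged groups against those libraries. Entries are named as in the deposited table, and no coordinates are given. Messenger RNA reads of the combined kit were not analysed here.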

Results

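Read counts of mature miRNA entries were compared across 27 libraries of CHO-K1 cells, their microparticles (MPs) and their exosomes. Each fraction was taken from a standard, an osmotic and an ammonia culture, with 3 libraries per group. Standard libraries held 132154 to 180764 counts in cells, 818539 to 1253633 in MPs and 2284857 to 2726446 in exosomes. Osmotic libraries held 8219782 to 10374430, 378397 to 1103990 and 26516 to 158836, and ammonia libraries 5236151 to 6841978, 1962086 to 2967003 and 116689 to 203816, in the same order. Detected entries ran from 427 to 562 per library in standard exosomes and from 127 to 201 in ammonia exosomes.

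**Figure D1:**
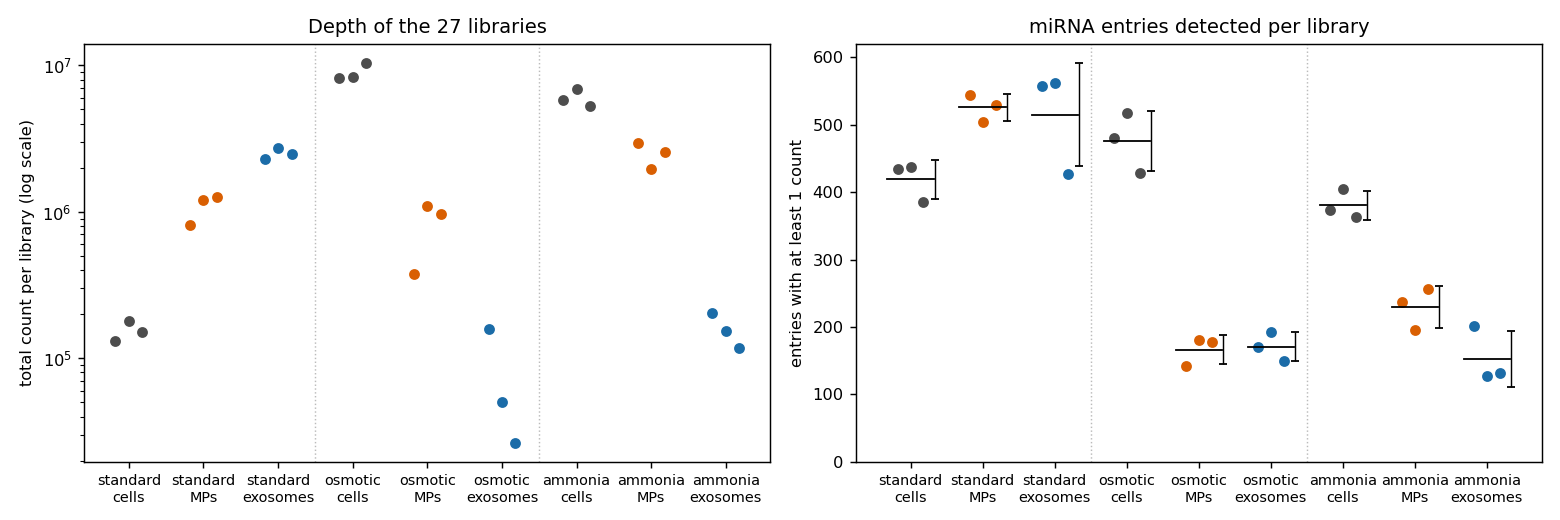
Total count per library on a log scale (left) and miRNA entries with at least 1 count (right) for the 9 groups, 1 point per library, with lines and bars on the right for the mean and SD over 3 libraries. Stressed MP and exosome libraries detected 127 to 256 entries, against 363 to 562 in all other libraries.

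In standard culture a few miRNAs made up most of the counts. In cells the most abundant entries were cgr-miR-21-5p, a widely expressed miRNA tied to growth and survival, at 14.3% ± 1.6 (SD, n = 3) of counts, cgr-miR-23a-3p at 11.3% ± 2.2 and cgr-miR-92a-3p, a member of the growth-linked miR-17~92 cluster, at 10.2% ± 3.2. These were followed by mmu-let-7c-5p, cgr-let-7f, cgr-let-7a, cgr-let-7b, cgr-miR-25-3p, cgr-miR-16-5p and mmu-miR-466i-5p, at 6.17% down to 2.58%. The same 3 entries led in MPs, with cgr-miR-92a-3p first at 14.1% ± 1.8, followed by cgr-miR-25-3p, mmu-let-7c-5p, cgr-miR-16-5p, cgr-let-7a, cgr-let-7f, cgr-miR-29a-3p and cgr-let-7b. In exosomes cgr-miR-92a-3p reached 20.6% ± 0.61, followed by cgr-miR-23a-3p at 13.98% ± 0.78, cgr-miR-25-3p at 7.21% ± 0.26 and cgr-miR-29a-3p at 5.10% ± 0.59, while cgr-miR-21-5p stood at 4.95% ± 1.2; mmu-miR-92a-3p, cgr-miR-22-3p, mmu-let-7c-5p, cgr-miR-16-5p and mmu-miR-24-3p completed the first 10. The let-7 family, which restrains growth and marks differentiated cells, took 24.3% ± 1.9 of counts in cells, 15.3% ± 1.9 in MPs and 8.57% ± 1.6 in exosomes. The miR-17~92 cluster and its paralogs went the other way, from 16.5% ± 3.4 to 23.1% ± 2.2 and 30.5% ± 0.54.

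The first question was how the cargo of MPs differs from the cells that shed them. In standard MPs against cells, cgr-miR-27a-3p (log2 fold change +1.83 ± 0.18, adjusted p = 7.29e-06), cgr-miR-181a-5p (+1.66 ± 0.21) and cgr-miR-19a (+1.96 ± 0.47) rose. Of the database entries known to overlap fragments of other RNA classes, mmu-miR-6240 (+3.86 ± 0.49) and mmu-miR-2137 (+3.60 ± 0.60) rose, and hsa-miR-4286 (−2.70 ± 0.68) and mmu-miR-3968 (−2.35 ± 0.27) fell. The entry mmu-miR-6481 was at 0 in cells and at least 8.96-fold higher in MPs, and mmu-miR-30e-5p averaged 79.9 ± 14.6 CPM in MPs against 1.84 ± 3.19 in cells, hsa-miR-4492 78.6 ± 61.4 against 1.84 ± 3.19 and hsa-miR-6089 52.6 ± 40.0 against 4.43 ± 7.67; hsa-miR-4508 rose by +2.64 ± 0.90. The largest falls, all of entries named for other species, were hsa-miR-11181-3p (−6.47 ± 0.94), mmu-miR-1187 (−5.14 ± 1.02), hsa-miR-10527-5p (−4.91 ± 0.70), hsa-miR-1244 (−4.84 ± 0.30), hsa-miR-95-5p (−4.83 ± 0.59), rno-miR-3473 (−4.72 ± 0.89), mmu-miR-3473a (−4.68 ± 0.47) and mmu-miR-706 (−4.34 ± 0.28, adjusted p = 4.92e-08).

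Lists moved in parts. Of 5 exactly matched let-7 members 1 fell, mmu-let-7e-5p (−1.29 ± 0.29), and 4 of the 9 in the extended list fell, with a median below 0 in all 4 scalings. The miR-17~92 list had 3 of 7 members rise (cgr-miR-93-5p, +0.91 ± 0.20) and the miR-232724 clusters 3 of 5. Rises were also seen for the miR-29 family, in 2 of 3 (cgr-miR-29b-3p, +1.16 ± 0.33; cgr-miR-29a-3p, +0.90 ± 0.20), for the miR-10, miR-99, miR-100 and miR-125 families, in 3 of 7 (4 when adjusted over the list alone), for the miR-181 family, in 1 of 4, and for the miR-15/16 family, in 1 of 5. No member of these 6 lists fell. In the miR-30 family 1 of 4 rose and 1 fell. Of miR-221 and miR-222, which often act together on cell cycle inhibitors, cgr-miR-221-3p fell (−1.46 ± 0.26) and mmu-miR-222-3p rose (+0.55 ± 0.19). Among the CHO engineering miRNAs 1 of 10 rose and 2 fell, the latter including hsa-miR-7-5p (−1.52 ± 0.22). Of 3 miRNAs linked to cell stress 1 rose, cgr-miR-132-3p (+1.40 ± 0.39), and of 7 vesicle-linked miRNAs 2 fell, including cgr-miR-320a (−0.91 ± 0.22; 1 fell when adjusted over the list alone). In the fragment list 2 of 10 rose and 3 fell (3 and 4 when adjusted over the list alone). None of the 2 miR-200 members, the 3 p53-linked miRNAs or the 3 tested markers of other cell types passed, and adjustment over the list alone changed no other count. In all, 110 of 351 entries passed, 55 higher and 55 lower, and 161 (45.9%) had no overlap between groups. Chance gives 10% for libraries of like depth, and the MP libraries were deeper than those of cells. The authors' effective library sizes split the calls 80 higher to 47 lower and moved the median of all entries by 0.19.

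Exosomes against cells gave the widest contrast of standard culture. Exosomes held more cgr-miR-181a-5p (log2 fold change +2.82 ± 0.21, adjusted p = 2.40e-07), mmu-miR-186-5p (+2.91 ± 0.30), cgr-miR-410-3p (+2.79 ± 0.44), mmu-miR-24-3p (+2.30 ± 0.23), cgr-miR-22-3p (+2.16 ± 0.24) and cgr-miR-27a-3p (+2.00 ± 0.18). The abundant cgr-miR-92a-3p (+0.84 ± 0.20, adjusted p = 0.00334) and cgr-miR-25-3p (+0.78 ± 0.17) rose as well, and cgr-miR-21-5p fell (−1.73 ± 0.25, adjusted p = 6.38e-05). For cgr-miR-23a-3p, among the most abundant in every fraction, the change of +0.08 ± 0.22 did not pass (adjusted p = 0.805). The largest rises by fold rest on very few counts in cells. Of these, mmu-miR-30e-5p averaged 104 ± 28.4 CPM in exosomes against 1.84 ± 3.19 in cells, mmu-miR-30a-5p 75.5 ± 6.11 against 4.06 ± 3.56, and cgr-miR-152-3p 75.2 ± 11.8 against 6.21 ± 5.66. The largest falls were again of entries named for other species. Both hsa-miR-11181-3p and rno-miR-3473 were at 0 in exosomes and at least 289-fold and at least 158-fold lower. Falls were also seen for hsa-miR-1244 (−8.29 ± 0.35, adjusted p = 4.40e-10), hsa-miR-95-5p (−8.06 ± 0.71), mmu-miR-3470b (−7.96 ± 0.93), hsa-miR-10527-5p (−7.55 ± 0.79), mmu-miR-3470a (−6.12 ± 0.49) and mmu-miR-466i-5p (−5.73 ± 0.31).

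**Figure D2:**
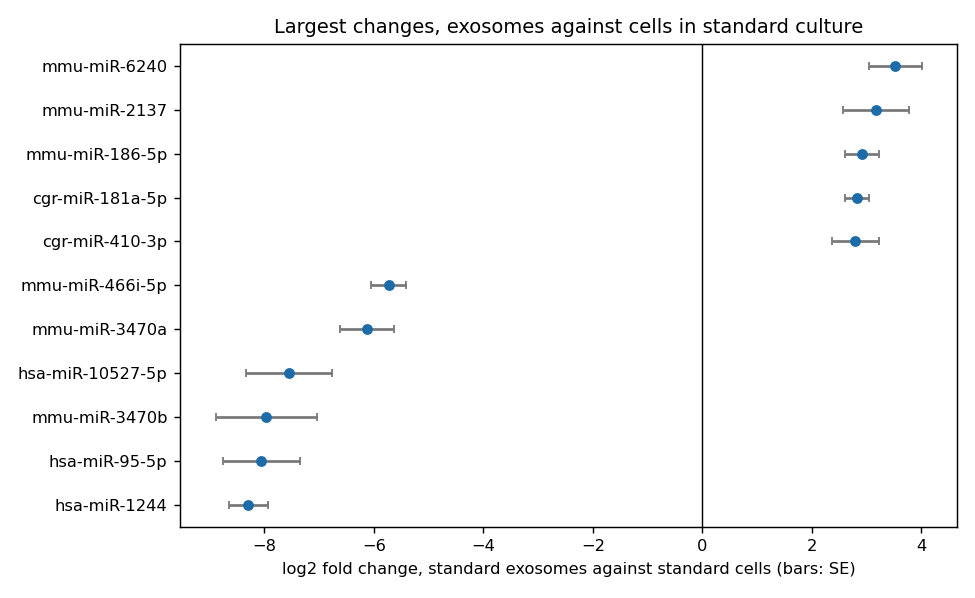
Log2 fold changes (points) with SE (bars, 3 libraries per group) of the largest rises and falls in standard exosomes against cells, for entries above 3 counts in both groups. The changes run from −8.29 for hsa-miR-1244 to +3.52 for mmu-miR-6240.

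The let-7 family was lower in exosomes in every scaling tried, although under the authors' sizes 2 of its 9 extended members lay higher and 1 of them passed. Of the 5 exact matches 3 fell, and 7 of the 9 extended members: mmu-let-7e-5p (−3.06 ± 0.30), cgr-let-7a (−2.56 ± 0.28) and cgr-let-7f (−2.52 ± 0.28) fell furthest. The miR-29 family had 2 of 3 members rise (mmu-miR-29c-3p, +2.17 ± 0.39; cgr-miR-29a-3p, +1.68 ± 0.20), the miR-181 family 3 of 4 and the miR-30 family 3 of 4, with cgr-miR-30b-5p falling (−1.34 ± 0.48). In the miR-232724 clusters 3 of 5 rose and hsa-miR-23b-3p fell (−1.33 ± 0.27). In the miR-17~92 list 4 of 7 rose and 1 fell; in the extended list cgr-miR-19a rose (+2.11 ± 0.46) and cgr-miR-20a fell (−1.09 ± 0.19). The miR-15/16 family, known to slow the cell cycle, had 4 of 5 members fall (mmu-miR-195a-5p, −1.48 ± 0.27; cgr-miR-16-5p, −0.74 ± 0.23) and rno-miR-15a-5p rise (+1.48 ± 0.30). In the miR-10, miR-99, miR-100 and miR-125 families 3 of 7 rose and 1 fell, and of miR-221 and miR-222 cgr-miR-221-3p fell (−0.69 ± 0.26) while mmu-miR-222-3p rose (+0.57 ± 0.19).

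Among the CHO engineering miRNAs 4 of 10 rose and 2 fell, hsa-miR-7-5p falling furthest (−2.70 ± 0.23). Of 3 stress-linked miRNAs cgr-miR-21-5p and mmu-miR-708-5p (−1.55 ± 0.21) fell and 1 rose. No exactly matched p53-linked miRNA of 3 passed, while in the extended list cgr-miR-192 (+2.30 ± 0.60) and cgr-miR-194 (+2.05 ± 0.27) rose. Of 7 vesicle-linked miRNAs only mmu-miR-203-3p passed, and it fell (−1.07 ± 0.26); the extended list adds cgr-miR-192. In the fragment list 3 of 10 rose, led by mmu-miR-6240 (+3.52 ± 0.49), and 4 fell, led by mmu-miR-6238 (−3.29 ± 0.45); 3 and 5 passed when adjusted over the list alone. Neither the miR-200 family (2 tested) nor the markers of other cell types (rno-miR-200c-3p +1.10 ± 1.01, mmu-miR-499-5p +0.50 ± 0.24, cgr-miR-486-5p +0.08 ± 0.20) had a member that passed. The comparison called 181 of 351 entries, 94 higher and 87 lower, with 57.0% free of overlap. Library size alone gave 110 higher to 72 lower and the authors' sizes 120 to 63, moving the median of all entries by 0.20 and 0.39. No list passed camera in any standard comparison (smallest adjusted p 0.107); with extended matching let-7 did for exosomes against cells (adjusted p = 0.00389, and adjusted p = 0.496 with an estimated correlation).

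Exosomes against MPs asked whether the vesicle types carry different miRNAs. Exosomes held more mmu-miR-186-5p (+2.01 ± 0.27, adjusted p = 4.01e-04), mmu-miR-324-5p (+1.93 ± 0.53), mmu-miR-24-2-5p (+1.89 ± 0.48), mmu-miR-1839-5p (+1.85 ± 0.36), cgr-miR-148b-3p (+1.66 ± 0.33), rno-miR-505-3p (+1.65 ± 0.33) and cgr-miR-192 (+1.58 ± 0.44), and less mmu-miR-6481 (−5.29 ± 0.82), hsa-miR-1244 (−3.45 ± 0.30), mmu-miR-6238 (−3.26 ± 0.44), cgr-miR-340-3p (−1.79 ± 0.42), cgr-miR-140-5p (−1.72 ± 0.32) and mmu-miR-466i-5p (−1.63 ± 0.26). The let-7 family was lower in all 4 scalings, with 2 of 5 exact and 6 of 9 extended members falling, mmu-let-7e-5p (−1.76 ± 0.29) and cgr-let-7a (−1.66 ± 0.27, adjusted p = 8.29e-04) among them. In the miR-15/16 family 4 of 5 fell. In the miR-30 family 3 of 4 rose (cgr-miR-30a-5p, +1.60 ± 0.36), in the miR-181 family 2 of 4 (3 when adjusted over the list alone), and in the miR-29 family 2 of 3, where the fall of cgr-miR-29b-3p passed under TMM scaling only. Of the vesicle-linked miRNAs cgr-miR-320a (+1.34 ± 0.22) and cgr-miR-423-5p (+0.93 ± 0.18) rose. Of the CHO engineering list 4 of 10 rose and 2 fell (6 and 2 when adjusted over the list alone), and cgr-miR-21-5p fell (−1.47 ± 0.25). In all 104 entries passed, 48 higher and 56 lower; the count was 69 without standard MPs replicate 2 and 54 without standard MPs replicate 3. The authors' sizes gave 67 higher to 42 lower, and medians moved by 0.15 with library size alone and 0.19 with the authors' sizes.

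Stressed cultures were dominated by let-7. In osmotic cells mmu-let-7c-5p led at 16.8% ± 2.8, followed by cgr-let-7a at 12.3% ± 1.2, cgr-let-7b, cgr-let-7f and cgr-miR-92a-3p. In osmotic MPs cgr-let-7b led at 21.9% ± 5.3, followed by mmu-let-7c-5p, cgr-let-7a, cgr-let-7f and cgr-miR-92a-3p. Osmotic exosomes were led by cgr-let-7b at 14.9% ± 2.2, mmu-let-7c-5p at 13.8% ± 1.8 and cgr-miR-320a at 7.81% ± 1.9, followed by cgr-miR-92a-3p and cgr-let-7a. Ammonia cells were led by cgr-let-7a at 17.1% ± 1.6, mmu-let-7c-5p at 16.6% ± 0.70, cgr-let-7b, cgr-let-7f and cgr-let-7d-5p. Ammonia MPs had the same 5 entries in front, mmu-let-7c-5p first at 19.1% ± 0.34, and ammonia exosomes cgr-let-7b at 20.6% ± 5.2, mmu-let-7c-5p at 13.1% ± 0.56, cgr-miR-92a-3p, cgr-let-7d-5p and cgr-let-7g-5p. The family took 54.9% ± 6.5, 66.0% ± 6.9 and 44.6% ± 3.3 of counts in osmotic cells, MPs and exosomes, and 66.0% ± 4.5, 67.1% ± 0.98 and 54.1% ± 6.3 in ammonia ones. Replicates of stressed vesicles differed strongly: entries of at least 50 CPM had a median coefficient of variation of 93.4% to 116% in the 4 stressed vesicle groups, against 15.5% to 30.4% in the other 5, and 11.1% to 32.0% of them had a library at 0.

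**Figure D3:**
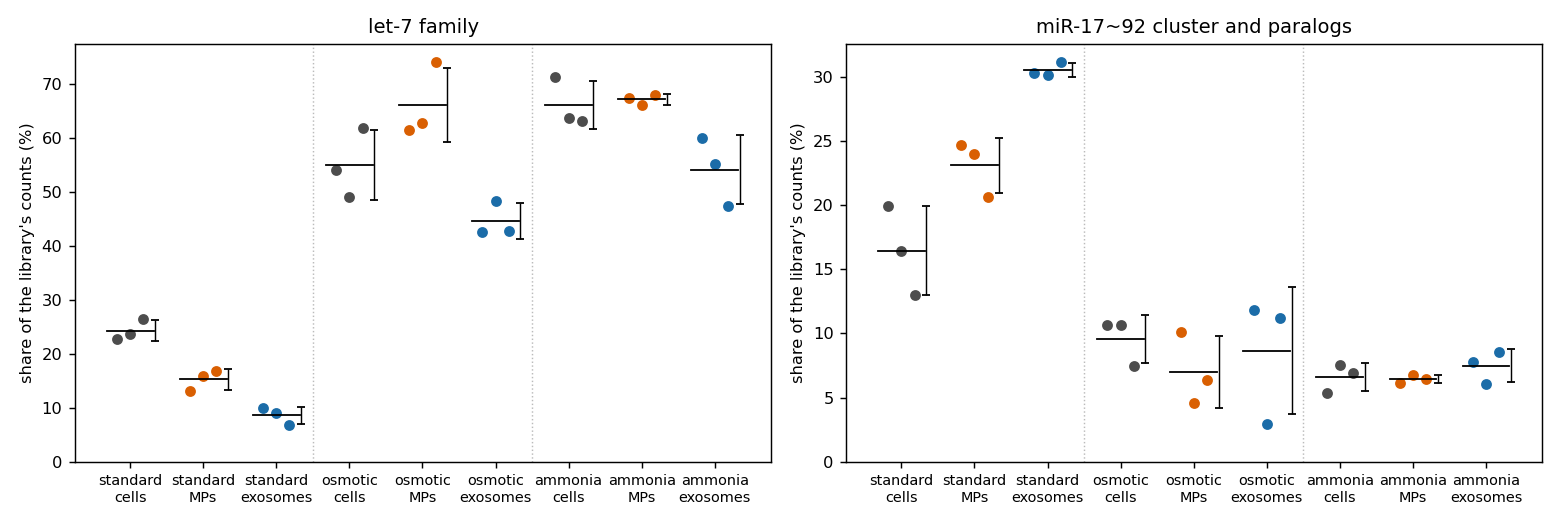
Share of each library's counts in the let-7 family (left) and in the miR-17~92 cluster with its paralogs (right), 1 point per library, with lines for the mean and bars for the SD over 3 libraries. The let-7 share is 8.57% to 24.3% on average in the 3 standard groups and 44.6% to 67.1% in the 6 stressed groups, which were made with another kit and pool.

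Within osmotic culture, MPs against cells showed a broad fall. In these MPs 33 of 103 entries of at least 50 CPM had a library at 0, so the bounds below cover counting error only. The largest falls were of entries at 0 in MPs: cgr-miR-31-5p was at least 741-fold lower, mmu-let-7a-1-3p at least 355-fold, hsa-miR-12135 at least 281-fold, rno-miR-222-3p at least 261-fold and hsa-miR-7-5p, a regulator of growth factor signalling, at least 249.7-fold. Rises were few: hsa-miR-3168 (log2 fold change +8.91 ± 2.21), hsa-miR-6089 (+8.32 ± 2.75) and cgr-let-7b (+2.11 ± 0.36, adjusted p = 0.00220). Members of the miR-17~92 list fell in 4 of 7 cases (cgr-miR-17-5p, −8.75 ± 2.42; cgr-miR-19b-3p, −8.52 ± 2.21), of the miR-232724 clusters in 3 of 5 (cgr-miR-27a-3p, −7.94 ± 2.42), of the miR-30 family in 2 of 4 and of the CHO engineering list in 7 of 11, and none rose. As a list let-7 stood higher than other entries by camera (adjusted p = 1.56e-04, and adjusted p = 0.120 with an estimated correlation), although only 1 of its 5 exact members rose (0 when adjusted over the list alone). Of 332 entries 171 passed, 10 higher and 161 lower, 89 of the latter at 0 in MPs; without a filter on low counts 17 passed. The count was 97, 108, 101, 1 and 41 without osmotic cells replicate 1, osmotic cells replicate 2, osmotic MPs replicate 1, osmotic MPs replicate 2 and osmotic MPs replicate 3.

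Osmotic exosomes against cells gave 0 called entries by edgeR, with 79 at an unadjusted p under 0.05 and 19 by DESeq2. Yet 213 of 332 entries (64.2%) had no overlap between the groups, where chance gives 10% for libraries of like depth. Exosome libraries held 26516 to 158836 counts and cell libraries 8219782 to 10374430. Part of this share can therefore come from entries too rare to be counted in exosomes. The count of 0 is not evidence that the 2 fractions are alike, and the share without overlap does not show how far they differ. Against osmotic MPs, exosomes held more cgr-miR-652-3p (+10.70 ± 2.68), cgr-miR-28-3p (+10.22 ± 2.29), cgr-miR-151-3p (+9.78 ± 2.41), cgr-miR-199a-3p, cgr-miR-103-3p, mmu-miR-29a-3p and cgr-miR-7a, the last at 5282 ± 4659 CPM against 0.604 ± 1.05, and less cgr-let-7a (−1.92 ± 0.36, adjusted p = 0.00838). The hamster-named cgr-miR-29a-3p did not pass (+3.84 ± 2.21, adjusted p = 0.256). By camera the miR-10, miR-99, miR-100 and miR-125 families stood lower than other entries (adjusted p = 2.25e-05, and adjusted p = 0.0177 with an estimated correlation), with 0 of 7 members past the edgeR test and medians below 0 in all 4 scalings. Camera, run under TMM scaling only, also put let-7 lower than other entries (adjusted p = 6.55e-05, and adjusted p = 0.0574 with an estimated correlation). The median log2 fold change of the list turned sign under RLE scaling and the authors' sizes, where camera was not run. These 8 calls, 7 higher and 1 lower, became 32, 16 and 23, all higher, under RLE scaling, library size alone and the authors' sizes. They numbered 3, 3 and 4 without osmotic MPs replicates 1, 2 and 3 and 13, 14 and 13 without osmotic exosomes replicates 1, 2 and 3.

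In ammonia MPs against cells, falls again outnumbered rises. Higher in MPs were mmu-miR-6238, at 0 in cells and at least 2643-fold higher, hsa-miR-4497 (111 ± 131 CPM against 0.0487 ± 0.0844), mmu-miR-2137 (+6.99 ± 2.22) and cgr-let-7b (+1.02 ± 0.35, adjusted p = 0.0317). At 0 in MPs were cgr-miR-365, at least 355-fold lower, mmu-let-7f-1-3p (at least 317-fold), cgr-miR-99b (at least 228-fold) and cgr-miR-1249 (at least 226-fold). The miR-17~92 list had 2 of 7 members fall (cgr-miR-19b-3p, −8.44 ± 2.17) and the fragment list 3 of 10 fall and 2 rise, the same counts as when adjusted over the list alone. In all 108 entries passed, 5 higher and 103 lower, with 59 without ammonia MPs replicate 2 and 7 without the filter. Ammonia exosomes against cells had 30 calls, 4 higher and 26 lower. Of those named, hsa-miR-3168 (+9.54 ± 2.28) and cgr-let-7b (+1.32 ± 0.35) rose, and cgr-miR-23a-5p (at least 50.02-fold) and cgr-miR-25-5p (at least 41.2-fold) were lower and at 0 in exosomes, while the most abundant fall, outside the naming rule and chosen after its values were seen, was cgr-let-7a (−2.02 ± 0.36). RLE scaling gave 15 calls and the authors' sizes 14, all higher, with the median of all entries moved by 2.54 and 3.46; library size alone gave 4 higher to 36 lower. Leaving out any of its 6 libraries left 1 (ammonia cells replicates 1 and 3, ammonia exosomes replicates 2 and 3), 2 (ammonia cells replicate 2) or 4 (ammonia exosomes replicate 1). Exosomes against MPs called cgr-let-7a alone (−1.83 ± 0.36, adjusted p = 0.0153), whose sign turned to +0.67 with RLE scaling, +0.68 with DESeq2 and +1.499 with the authors' sizes. The call was lost without ammonia MPs replicate 1 or 3 (0 calls each). Counts were 10 without ammonia MPs replicate 2 and 4, 2 and 4 without ammonia exosomes replicates 1, 2 and 3. There the miR-10, miR-99, miR-100 and miR-125 families were lower by camera (adjusted p = 0.00363, and adjusted p = 0.111 with an estimated correlation), in all 4 scalings by median.

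Osmotic and ammonia libraries share kit and pool, so comparing them asks how the stresses differ. In cells, edgeR called 0 of 332 entries (13 at an unadjusted p under 0.05; 0 by DESeq2), the smallest adjusted p being 0.245; simulated changes of 16-fold were not recovered in that fit either. A fit of the 6 cell libraries alone, which did recover simulated changes, also called 0. Camera placed the let-7 list lower in osmotic cells (adjusted p = 0.0246, and adjusted p = 0.508 with an estimated correlation), with 0 of 5 members called and the same sign of the median in all 4 scalings. In MPs, osmotic culture had less cgr-miR-28-3p (−9.51 ± 2.23), mmu-miR-6412 (−9.45 ± 2.33), cgr-miR-7a (0.604 ± 1.05 CPM against 696 ± 650.0) and cgr-miR-139-5p (0.881 ± 1.53 CPM against 1168 ± 1172), and cgr-miR-15b-3p, rno-miR-222-3p, mmu-miR-296-3p and cgr-miR-324-3p were at 0 in osmotic MPs and at least 346-fold, at least 325-fold, at least 201-fold and at least 189-fold lower. Of the CHO engineering list 4 of 11 fell (5 when adjusted over the list alone), and of the miR-232724 clusters 2 of 5 (3 when adjusted over the list alone; cgr-miR-27a-3p, −8.17 ± 2.44; hsa-miR-23b-3p, −6.88 ± 2.15), with camera adjusted p = 0.0430, and adjusted p = 0.173 with an estimated correlation. Both tested p53-linked miRNAs, cgr-miR-34c-5p (+8.18 ± 2.69) and cgr-miR-34b-5p (at 0 in ammonia MPs), rose, but cgr-miR-34b-5p was found in 1 of 3 osmotic libraries, and the list took 0.108%, 9.06e-05% and 0.247% of counts in osmotic MPs replicates 1, 2 and 3, against at most 2.72e-04% in ammonia MPs. The 64 calls, 13 higher and 51 lower, fell to 0 with a fit of the compared groups alone, and to 25, 0 and 0 without osmotic MPs replicates 1, 2 and 3. Only 10.5% of entries had no overlap in MPs, near the 10% of chance, against 24.7% in cells and 7.53% in exosomes. In exosomes edgeR called 0 entries, with 61 at an unadjusted p under 0.05 and 34 by DESeq2; the count was 1 and 2 without ammonia exosomes replicates 1 and 2.

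Stress against standard culture was the remaining question, and here stress, kit and pool change together, so no difference can be assigned to stress. The trimming and length limit of reads, named in the file headers for the stressed libraries, may change too. In cells both stresses showed more let-7: cgr-let-7d-5p (+4.14 ± 0.58, adjusted p = 3.22e-05 in osmotic and +5.09 ± 0.60 in ammonia culture), mmu-let-7c-5p (+2.22 ± 0.28 and +2.54 ± 0.28) and cgr-let-7a (+1.96 ± 0.36 and +2.78 ± 0.37) rose, 3 of 5 exact (4 when adjusted over the list alone) and 6 of 9 extended members in each. The family's median was above 0 in all 4 scalings, but RLE and the authors' sizes left 1 member past the test. Camera gave the exact list adjusted p = 0.0109 in ammonia cells, and adjusted p = 0.174 with an estimated correlation. Both also had more cgr-miR-221-3p (+3.49 ± 1.14 and +4.22 ± 1.18), mmu-miR-30d-5p (+3.20 ± 0.62 and +2.74 ± 0.61), cgr-miR-34c-5p (+6.39 ± 1.94 and +5.62 ± 1.87) and cgr-miR-29b-5p (+7.17 ± 1.70 and +7.64 ± 1.73). hsa-miR-12135, mmu-miR-107-3p and cgr-miR-199a-5p were at 0 in standard cells and at least 52.95-fold, at least 17.9-fold and at least 16.6-fold higher in osmotic cells, and at least 32.0-fold, at least 24.3-fold and at least 9.42-fold higher in ammonia cells. In the other direction mmu-miR-706 was at 0 in both stressed cell groups, at least 75561-fold lower in osmotic and at least 50168-fold lower in ammonia cells, and hsa-miR-10527-5p (at least 5924-fold and at least 3933-fold) and hsa-miR-4468 (at least 3642-fold and at least 2418-fold) were also at 0. In ammonia cells hsa-miR-1244 was at 0 (at least 32527-fold lower), and in osmotic cells it averaged 0.0406 ± 0.0702 CPM against 5468 ± 2126. Of the miR-15/16 family mmu-miR-195a-5p fell in osmotic cells (−5.44 ± 1.59) and averaged 0.0487 ± 0.0844 CPM in ammonia cells against 1587 ± 372. In both, mmu-miR-29c-3p (−3.49 ± 1.06 and −4.30 ± 1.11) fell, and cgr-miR-21-5p fell in ammonia cells (−2.51 ± 0.74) but not past the test in osmotic cells (−1.38 ± 0.71, adjusted p = 0.169). Calls numbered 76 (39 higher, 37 lower) and 103 (44 and 59) of 420. The split depended on scaling: osmotic cells gave 10 to 44 with RLE, 16 to 40 with library size and 10 to 38 with the authors' sizes, and ammonia cells 10 to 79, 16 to 73 and 12 to 65, the osmotic medians moving by −1.24, −0.75 and −0.83. Osmotic calls were 41, 36 and 42 without standard cells replicates 1, 2 and 3, and ammonia calls 67 without standard cells replicate 2.

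In MPs, let-7 was higher under both stresses in all 4 scalings. All 5 exact members rose in osmotic MPs and 4 in ammonia MPs (5 when adjusted over the list alone). In the extended list 8 of 9 rose in each, led by cgr-let-7d-5p (+5.57 ± 0.62, adjusted p = 2.64e-07, and +5.86 ± 0.63), mmu-let-7e-5p (+4.95 ± 1.16 and +3.76 ± 1.10) and cgr-let-7b (+4.94 ± 0.39 and +4.51 ± 0.38). Camera called the list in both (adjusted p = 3.07e-08 and 2.04e-07), and again with an estimated correlation (adjusted p = 0.00485 and 0.00792). The vesicle-linked cgr-miR-423-5p (+4.46 ± 0.67 and +4.11 ± 0.66) and cgr-miR-320a (+4.19 ± 0.83 and +5.06 ± 0.87) and hsa-miR-3168 (+8.04 ± 1.80 and +6.75 ± 1.70) also rose, as did cgr-miR-221-3p (+5.14 ± 1.23 and +6.41 ± 1.31) and, in ammonia MPs, mmu-miR-296-3p (+8.09 ± 1.66). Of the miR-15/16 family 3 of 6 tested members fell in each, and of the miR-29 family 3 of 3 in osmotic and 2 of 3 in ammonia MPs; camera called neither list (adjusted p = 0.270 and 0.222 for miR-15/16, 0.143 and 0.303 for miR-29). Of single entries mmu-miR-195a-5p was at 0 in both, at least 1097-fold and at least 3350.3-fold lower, and cgr-miR-29b-3p too (at least 377-fold and at least 1151-fold); cgr-miR-322-5p and cgr-miR-369-3p were at least 1765-fold and at least 809-fold lower in osmotic MPs, and mmu-miR-706 at least 1088-fold lower in ammonia MPs. The miR-232724 clusters had 4 of 5 members fall in osmotic MPs (cgr-miR-27a-3p, −9.43 ± 1.98) and 0 in ammonia MPs. Calls numbered 194 (35 higher, 159 lower) and 188 (52 and 136). Library size alone gave 19 to 219 in osmotic MPs, and the ammonia split was 21 to 202 with RLE, 21 to 203 with library size and 30 to 176 with the authors' sizes.

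In exosomes, let-7 was again higher under both stresses in all 4 scalings, with 4 of 5 exact and 7 of 9 extended members rising in each: mmu-let-7e-5p (+4.95 ± 1.16 and +3.98 ± 1.11), cgr-let-7b (+3.86 ± 0.37, adjusted p = 5.32e-08, and +4.93 ± 0.39), cgr-let-7d-5p (+3.51 ± 0.56 and +4.85 ± 0.60) and mmu-let-7c-5p (+2.77 ± 0.29 and +3.28 ± 0.29). Camera called the list (adjusted p = 0.0170 in osmotic and 4.90e-04 in ammonia exosomes), which was lost with an estimated correlation (adjusted p = 0.136 and adjusted p = 0.104 with an estimated correlation). The miR-17~92 list was lower in all 4 scalings (camera adjusted p = 0.0170 and 0.0213; adjusted p = 0.136 and adjusted p = 0.159 with an estimated correlation), 2 of 7 members falling in osmotic and 5 of 7 in ammonia exosomes (4 and 6 when adjusted over the list alone), among them cgr-miR-17-5p (−4.38 ± 1.43 and −7.21 ± 1.64). In ammonia exosomes 4 of 7 members of the miR-10, miR-99, miR-100 and miR-125 families fell (camera adjusted p = 0.0341, and adjusted p = 0.159 with an estimated correlation), mmu-miR-99a-5p furthest (−7.57 ± 2.08). cgr-miR-322-5p was at 0 in both, at least 87.9-fold and at least 177-fold lower, as were cgr-miR-18a-5p (at least 55.4-fold and at least 112-fold) and mmu-miR-195a-5p (at least 51.6-fold and at least 104-fold), and in ammonia exosomes cgr-miR-369-3p (at least 150.98-fold) and mmu-miR-350-3p (at least 122-fold), while hsa-miR-3168 (+10.84 ± 1.99 and +12.62 ± 2.11) rose, and mmu-miR-574-5p in osmotic exosomes (+5.15 ± 1.23). Calls numbered 68 (17 higher, 51 lower) and 139 (28 and 111). Osmotic splits were 19 to 26 with RLE and 22 to 11 with the authors' sizes, and ammonia splits 34 to 62, 17 to 160 with library size and 38 to 26. Osmotic calls were 41, 41 and 43 without standard exosomes replicates 1, 2 and 3, and 22 and 41 without osmotic exosomes replicates 1 and 2.

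**Figure D4:**
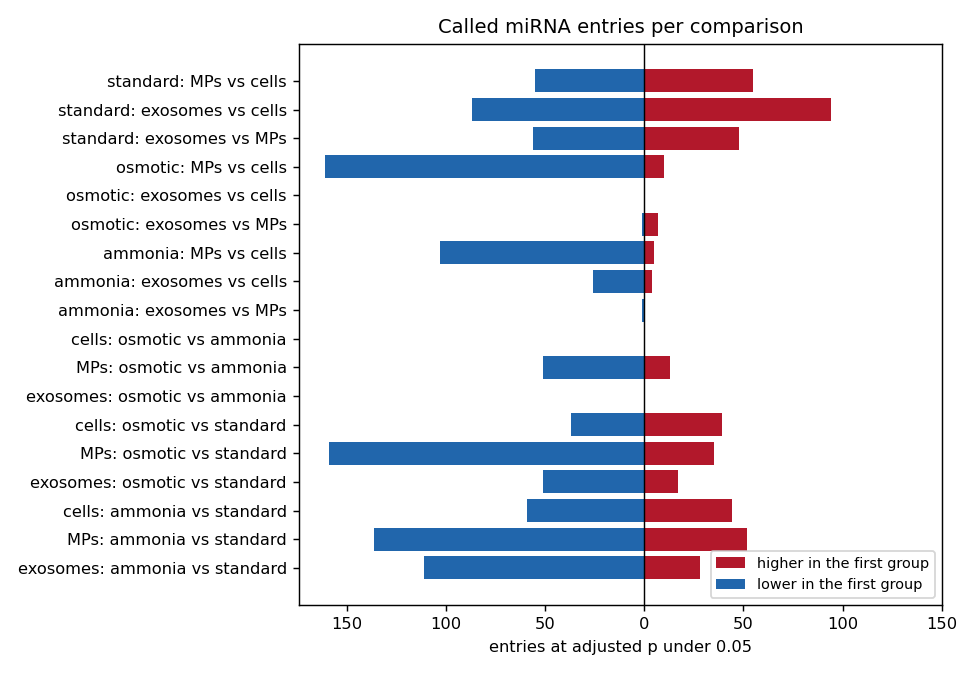
Entries with an edgeR adjusted p under 0.05 in each of the 18 comparisons of groups, as bars to the right for entries higher and to the left for entries lower in the first group named. Standard exosomes against cells called 181, osmotic MPs against standard MPs 194, and 3 comparisons called 0.

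Many of the same entries differed from standard culture in both stressed cultures, which share kit and pool. In cells 64 entries passed in both with the same direction (32 higher, 32 lower), where independent lists would share 4.09 and 5.198. In MPs there were 123 (22 and 101, against 4.33 and 51.5), with 7 in opposite directions. In exosomes there were 61 (13 and 48, against 1.13 and 13.5), with 1 in opposite directions. Across entries, which are not independent replicates, fold changes correlated at 0.84, 0.53 and 0.63, against means of 0.31, 0.09 and 0.08 in 30 simulations of unchanged groups that share the standard libraries, where 0 calls were shared. Their covariance was 15.4, 13.5 and 13.3, against simulated 0.882, 0.247 and 0.453. The 3 standard libraries of a fraction cannot be split, so part of the excess may come from the shared controls, and the kit and pool are shared too.

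Whether vesicles differ from their cells in the same way in every culture was tested as an interaction. In exosomes minus cells, the change of cgr-let-7b stood higher under osmotic (+1.83 ± 0.47, adjusted p = 0.0233) and ammonia stress (+2.38 ± 0.47, adjusted p = 0.00497) than in standard culture. Its means in cells and exosomes were 37361 and 13102 CPM in standard, 88865 and 148843 in osmotic, and 100605 and 205692 in ammonia culture. The change of hsa-miR-3168 also stood higher (+15.04 ± 2.48 and +13.88 ± 2.43), with means of 20.4 and 0.489 CPM in standard cells and exosomes. In MPs minus cells, the changes of hsa-miR-3168 (+12.24 ± 2.34), mmu-miR-6238 (+6.64 ± 1.98) and mmu-miR-3473a (+6.21 ± 1.70) stood higher under osmotic stress than in standard culture, where mmu-miR-3473a averaged 416 CPM in cells and 16.95 in MPs. The falls named were entries at 0 in stressed vesicles and present in the matching cells: cgr-miR-199a-5p averaged 108 CPM in osmotic cells and 0 in osmotic MPs, against 0 and 1.64 in standard ones, cgr-miR-31-5p 906 CPM in osmotic cells and 0, against 238 and 278. Likewise cgr-miR-615-3p averaged 71.5 in ammonia cells and 0 in ammonia MPs, against 15.3 and 51.5. For exosomes minus cells mmu-miR-107-3p was named in both stresses, at 116 and 157 CPM in osmotic and ammonia cells and 0 in their exosomes, against 0 and 0.950 in standard ones. Its change between stressed and standard exosomes was not called. Osmotic against standard culture called 162 entries in MPs (12 higher, 150 lower) and 42 in exosomes (5 and 37), and ammonia against standard 92 (10 and 82) and 90 (3 and 87); again kit and pool change with the stress. For exosomes RLE scaling gave 6 higher to 0 lower and 11 to 0, library size 4 to 12 and 4 to 74, and the authors' sizes 5 to 0 and 8 to 0. The osmotic exosome count was 19, 9 and 8 without standard cells replicates 1, 2 and 3, 26 without standard exosomes replicate 2, 18 without osmotic cells replicate 2, and 16 and 22 without osmotic exosomes replicates 1 and 2. The ammonia exosome count was 58 and 55 without standard cells replicates 2 and 3. Between osmotic and ammonia culture, rno-miR-222-3p was the only call for MPs (adjusted p = 0.0483), at 319 CPM in osmotic cells and 0 in osmotic MPs against 53.7 and 397 in ammonia culture. It was lost (0 calls) without any 1 osmotic cell, osmotic MP or ammonia cell library, and 19 and 2 entries were called without ammonia MPs replicates 2 and 3. For exosomes edgeR called 0, with 26 at an unadjusted p under 0.05 and 6 by DESeq2, and 1 without ammonia exosomes replicate 1 or 2. Across 420 entries, vesicle minus cell changes correlated at 0.40 (MPs) and 0.45 (exosomes) between the stresses, and at −0.08 to 0.03 between a stress and standard culture.

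The authors' deposited table of 18 contrasts called 221 entries for standard exosomes against cells and shared 160 of the 181 called here. The scaling behind it need not be the authors' effective library sizes. For ammonia exosomes against cells it called 13 entries higher and 93 lower, where those sizes gave 14, all higher. The authors' deposited table shared 102 of 104 for exosomes against MPs and 101 of 110 for MPs against cells. The authors' deposited table called 76 entries between osmotic and ammonia cells, where edgeR called 0 here, and 310 and 340 between stressed and standard cells, sharing 70 of 76 and 96 of 103. For stressed vesicles the overlap with the authors' deposited table was often smaller. Against cells it was 75 of 171 for osmotic MPs (106 called there), 92 of 108 for ammonia MPs (113) and 11 of 30 for ammonia exosomes (106). The 106 of osmotic MPs were 34 higher and 72 lower, against 10 and 161 here. Against standard culture it was 126 of 194 for osmotic MPs (142), 175 of 188 for ammonia MPs (209), 27 of 68 for osmotic exosomes (62, with 34 higher and 28 lower, against 17 and 51 here) and 59 of 139 for ammonia exosomes (79). Between osmotic and ammonia MPs it was 62 of 64 (102). The authors' deposited table called 84 entries for ammonia and 58 for osmotic exosomes against MPs, where 1 and 8 were called here. The 84 were 6 higher and 78 lower. The 58 were 28 higher and 30 lower, against 7 and 1 here. It also called 22 for osmotic exosomes against cells and 48 between osmotic and ammonia exosomes, where edgeR called 0 here. Every entry called here had the same sign in the authors' deposited table.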

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

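The tests of depth, of a selected set and of read sampling for the poorly replicated vesicle libraries, both tests of the let-7 share and the test of entry species were chosen only after the result was seen. Of the 18 comparisons of groups, each has 10 splits of its libraries, too few for a share under 0.05. The real counts and the highest of the other splits were 110 and 0 for standard MPs against cells, 181 and 0 for exosomes against cells, and 104 and 0 for exosomes against MPs. In osmotic culture they were 171 and 0, 0 and 0, and 8 and 0, and in ammonia culture 108 and 0, 30 and 0, and 1 and 0, in the same order. Osmotic against ammonia gave 0 and 0 in cells, 64 and 51 in MPs, and 0 and 2 in exosomes. Osmotic against standard gave 76 and 0, 194 and 0, and 68 and 0 in cells, MPs and exosomes, and ammonia against standard 103 and 0, 188 and 0, and 139 and 0. The real split alone gave the real count (1 of 10), except where 0 entries were called (10 of 10).

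A tested difference between cultures in the change from cells to vesicles singled out 5 counts. Between osmotic and standard culture 162 entries changed differently in MPs and 42 in exosomes, and between ammonia and standard culture 92 and 90. Of 100 splits, counts as large came from 2 (highest other 173), 2 (99), 3 (207) and 1 (65). Of the splits 98, 98, 98 and 99 put libraries of both kits into the same group, and 79, 79, 82 and 83 of those called 0. The kit thus bears on these shares, and the splits do not decide about chance. The highest other split exchanges all 3 vesicle libraries of each culture for both MP counts and for osmotic exosomes. Apart from its sign, the contrast then becomes the sum of the stressed minus standard differences in vesicles and in cells, a structure of the samples. For ammonia exosomes the highest other split exchanges 2 of 3. Kit and pool cannot be told apart from the stress in all 4. Between osmotic and ammonia culture 1 entry changed differently in MPs, and 28 of 100 splits gave as many (highest other 37), so chance is not excluded; for exosomes the count of 0 by edgeR (26 at an unadjusted p under 0.05; 6 by DESeq2) was reached by all 100 splits, the highest other giving 1.

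Libraries of stressed MPs and exosomes detected fewer entries, and 39.4% to 48.6% of a group's entries were found in all 3 replicates, against 53.5% to 64.0% in the other 5 groups. Depth alone is argued against, since stressed cell libraries thinned to the same totals detected 1.95 times as many entries (median over 12 libraries). Replicates of these vesicles ranked entries differently, with a highest Spearman correlation of 0.603 across entries, which are not independent replicates. This meets the limit set against a selected set of miRNAs in these vesicles. Noise between replicates lowers rank agreement with or without such a set, so the test cannot decide and a selected set stays open. A small number of RNA molecules would put large counts in single replicates. Entries found in 1 of 3 replicates had a median of 1 count in each of the 4 stressed vesicle groups. By the limit set before the test this goes against it for most of these entries, though not for the largest such counts, up to 4326. The same median was 6.5 in osmotic and 20 in ammonia cells, which replicated better, so this measure cannot decide. Abundant entries were missing from single libraries too: 33 and 42 entries of at least 50 CPM (32.0% and 25.8%) had a library at 0 in osmotic and ammonia MPs, and 8 (11.1%) in ammonia exosomes. Sampling of reads at each group's pooled share is argued against as the source of these, since they number at least 862187 times (MPs) and 4170 times (ammonia exosomes) those expected. In osmotic exosomes, with the lowest totals, 20 such entries (17.4%) are 2.67 times the expected 7.497, so sampling stays open there for part of them. What else lies behind the poor replication of abundant entries, a small number of molecules included, stays open.

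The let-7 share of counts was higher in stressed than in standard libraries, with the lowest stressed library at least 22.6 percentage points above the highest standard library of its fraction. Kit or pool and stress cannot be told apart for this, since they change together in all 27 libraries. Both stresses lie on the same side in cells, MPs and exosomes, which either explanation allows. A growth arrest under stress, with which let-7 is often tied, remains untested.

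Many entries that were lower in standard exosomes than in standard cells were near 0 in stressed cells. Low depth of the stressed cell libraries is argued against by the totals alone, at least 5236151 counts against at most 180764 in standard cells. Of the 26 entries at under 1/16 of their standard level, 100% would have more than 3 counts in the shallowest stressed cell library. The totals fixed that outcome in advance, so it adds no support. Among the 87 lower entries, the 51 named for other species had a median log2 ratio of stressed to standard cells of −3.31 against −0.81 for the 36 hamster-named ones, a difference of −2.51 (two-sided permutation p = 0.0027), and 14 of them against 0 were at 0 in stressed cells. Among higher entries 38 and 56 carried such names (Fisher's exact p = 0.0174). Both tests treat entries as independent replicates, which they are not, since near-identical entries can share reads. The lower entries were also chosen on the standard-cell values that enter the ratio. Fragments of other RNA counted with the combined mRNA and miRNA kit may explain this. An effect of stress on these entries stays open, since the kit, and possibly the trimming and length limit of reads, change with it.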

How the results depend on the processing

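The tests with the authors' effective library sizes, without the 6 stressed exosome libraries, with hamster-named entries alone and with extended lists were chosen only after the result was seen. Simulated changes show what depth and the spread estimated over all libraries of a fit allow. In standard exosomes against cells 46.8% of 2-fold, 86.2% of 4-fold and 100% of 16-fold changes were recovered, with 5.66% of calls false. In osmotic MPs against cells 1.64% of 16-fold changes were recovered, in osmotic against standard MPs 7.69% (16.7% of calls false, out of few calls in a single simulation), and in osmotic against ammonia cells 0%, against 65.6% in a fit of those 6 libraries. Of 3619 values of named entries under an alternative, 3109 kept direction and call, 505 kept direction without the call and 5 changed sign. The cause of the changes below was not tested, except where fewer entries or libraries took part.

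Scaling changed the call counts of stressed exosomes in many comparisons. Against standard culture, RLE scaling moved the medians more in stressed cells and MPs than in stressed exosomes. RLE scaling gave 2 calls for osmotic exosomes against cells, 32 against MPs, 15 and 15 for ammonia exosomes against cells and MPs, and 45 for osmotic against standard exosomes. It gave 40 shared entries in exosomes between the stresses and, for the interactions, 0 (MPs, osmotic against ammonia), 6 (exosomes, osmotic against standard) and 11 (exosomes, ammonia against standard). With library size alone osmotic exosomes against MPs gave 16, ammonia exosomes against MPs 0, and the osmotic exosome interaction with standard culture 16. The authors' sizes gave 1 and 23 for osmotic exosomes against cells and MPs, 14 and 11 for ammonia ones, 1 for osmotic against ammonia exosomes, 48 for osmotic against standard cells, and 33 and 64 for osmotic and ammonia against standard exosomes. For the same interactions as under RLE scaling they gave 0, 5 and 8. The fall of cgr-let-7a in ammonia exosomes against MPs became a log2 fold change of 0.67 with RLE, 0.68 with DESeq2 and 1.499 with the authors' sizes, none of which passed. The authors' sizes moved the median of all entries by 0.19 for standard MPs against cells. Medians moved, under RLE, library size and the authors' sizes in this order, by 1.66, −0.05 and 1.71 for osmotic exosomes against cells, 0.12, −0.65 and 0.12 for osmotic MPs against cells, and 0.35, 0 and 0.68 for osmotic exosomes against MPs. For ammonia culture the same 3 shifts were −0.05, −0.26 and 0.11 (MPs against cells) and 0.69, 0.07 and 0.69 (exosomes against MPs), with −0.18 under library size for exosomes against cells. Against standard culture they were −0.83, −1.11 and −0.79 for osmotic MPs, 0.57, −0.35 and 1.02 for osmotic exosomes, −1.39, −1.01 and −0.76 for ammonia cells, −1.56, −1.51 and −0.98 for ammonia MPs, and 0.48, −0.81 and 1.39 for ammonia exosomes. Library size alone moved osmotic against ammonia culture by 0.35 in cells and 0.24 in exosomes. For the interactions between the stresses the 3 shifts were −0.03, −0.48 and −0.08 (MPs) and −0.36, −0.18 and −0.67 (exosomes). For those with standard culture they were 0.50, −0.24 and 0.12 (osmotic MPs), 1.82, 0.48 and 1.84 (osmotic exosomes), −0.02, −0.31 and −0.14 (ammonia MPs), and 2.74, 0.39 and 2.94 (ammonia exosomes).

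DESeq2 gave 19 and 78 calls for osmotic exosomes against cells and MPs, 49 and 74 for ammonia ones, 34 for osmotic against ammonia exosomes, and 53 and 6 for the MP and exosome interactions between the stresses. Without a filter on low counts, osmotic culture gave 17 (MPs against cells), 4 (exosomes against cells) and 21 (exosomes against MPs), ammonia culture 7 (MPs against cells) and 18 (exosomes against cells), and exosomes 5, 32 and 45 for osmotic against ammonia, osmotic against standard and ammonia against standard. Shared entries in exosomes were 16. The interactions without a filter gave 48 (MPs) and 5 (exosomes) between the stresses, and 8 and 11 in exosomes for osmotic and ammonia against standard culture.

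Counts summed over species names gave 2 for osmotic exosomes against cells, 74 and 10 for ammonia exosomes against cells and MPs, and 0 for the MP interaction between the stresses. Hamster-named entries alone mean fewer entries tested. They gave 42, 85 and 55 for standard MPs against cells, exosomes against cells and exosomes against MPs, 98 and 57 for osmotic and ammonia MPs against cells, and 41 for osmotic against ammonia MPs. Osmotic against standard culture gave 6, 96 and 17 in cells, MPs and exosomes, and ammonia against standard 33, 106 and 37. Interactions gave 0 (MPs, osmotic against ammonia), 51 and 1 (MPs and exosomes, osmotic against standard), and 35 and 3 (ammonia against standard).

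A fit of the compared groups alone gave 3 for osmotic exosomes against MPs, 4 and 0 for ammonia exosomes against cells and MPs, 0 and 1 for osmotic against ammonia MPs and exosomes, 191 and 138 for osmotic against standard cells and exosomes, and 171 for ammonia against standard cells. Interactions gave 16 (MPs, osmotic against ammonia), and 102 and 33 (exosomes, osmotic and ammonia against standard). Whether replicate numbers pair the libraries stays open. Within a culture, same-number correlations ran from −0.064 to 0.161, and those of other numbers from −0.189 to 0.107. In standard culture 2 of 9 same-number pairs lay above 0.1. Between cultures, same-number correlations within a fraction ran from −0.296 to 0.147. Such weak values cannot exclude pairing. The main fits carry no block, and one is given here only. With the replicate block, osmotic exosomes against MPs gave 1, ammonia exosomes against cells 2, osmotic against ammonia cells 1 and MPs 0, and the MP interaction between the stresses 0. Without the 6 stressed exosome libraries, osmotic against ammonia MPs gave 21 and the MP interaction 16.

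Of 14 list calls by camera 3 held with an estimated correlation, and fry called 116. Agreement of vesicle minus cell changes, over entries of at least 50 CPM, was 0.29 (MPs, osmotic and ammonia), 0.092 (MPs, ammonia and standard), −0.029 (exosomes, osmotic and standard) and 0.026 (exosomes, ammonia and standard).

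Leaving out each library in turn gave 54 to 93 calls for standard exosomes against MPs, 1 to 136 for osmotic MPs against cells, 3 to 14 for osmotic exosomes against MPs, 59 to 106, 1 to 4 and 0 to 10 for ammonia MPs against cells, exosomes against cells and exosomes against MPs, 0 to 61 and 0 to 2 for osmotic against ammonia MPs and exosomes, 36 to 63 and 22 to 50 for osmotic against standard cells and exosomes, and 67 to 102 for ammonia against standard cells. Interactions ran from 0 to 19 (MPs) and 0 to 1 (exosomes) between the stresses, and from 8 to 55 and 55 to 107 in exosomes for osmotic and ammonia against standard culture. The exosome agreement between the stresses ran from 0.35 to 0.46. Single libraries turned the sign of mmu-miR-3473a in the osmotic exosome interaction (−1.83 without osmotic exosomes replicate 1, up to 7.77) and of cgr-miR-146b-3p in the ammonia MP interaction (−1.14 without ammonia MPs replicate 1, up to 11.4).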

Other observations

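The tests of the let-7b to let-7a ratio and all values in this part were chosen only after the result was seen. Some miRNA groups not described as shares above followed the fractions of standard culture. The miR-29 family, which restrains matrix genes, took 1.42% ± 0.27 (SD, n = 3) of counts in standard cells, 2.75% ± 0.40 in MPs and 5.14% ± 0.59 in exosomes, and its median change was above 0 in all 4 scalings for each vesicle type against cells. The miR-232724 clusters took 12.3% ± 2.2, 14.8% ± 0.085 and 17.5% ± 1.3, and the miR-30 family 0.382% ± 0.18, 0.696% ± 0.038 and 1.25% ± 0.031. The miR-15/16 family took 5.06% ± 0.75, 5.47% ± 0.68 and 3.38% ± 0.45. In stressed cells these shares were lower at 0.219% (osmotic) and 0.136% (ammonia) for miR-29, 0.902% and 0.720% for miR-15/16, and 3.14% and 2.498% for miR-232724, and higher at 2.14% and 1.19% for miR-30, with kit and pool changing too.

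The means of hsa-miR-3168, among the largest rises named, and of 1 p53-linked miRNA are given here by fraction. hsa-miR-3168 averaged 0.562 CPM in osmotic cells, 182 in osmotic MPs and 827 in osmotic exosomes, and 3.69, 76.0 and 1994 in the ammonia fractions, whereas in standard culture it went the other way, from 20.4 to 2.16 and 0.489. Against cells edgeR called it in osmotic MPs and ammonia exosomes, and not in osmotic exosomes (adjusted p = 0.0587) or ammonia MPs (adjusted p = 0.0574). The p53-linked cgr-miR-34c-5p averaged 1439.9 CPM in osmotic cells and 645 in ammonia cells, and 22.1 and 11.8 in the matching exosomes, which edgeR did not call (adjusted p = 0.178 and 0.102).

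Because let-7b led the stressed exosomes while let-7a led ammonia cells, the log2 ratio of let-7b to let-7a counts was taken in each library, which no scaling between libraries affects. The ratio was higher in exosomes than in cells by 0.85 in standard, 2.24 in osmotic and 3.39 in ammonia culture, and in MPs by 0.10, 1.49 and 1.18. An exact two-sided permutation p within cultures of 0.00025 for exosomes decides nothing here, because the pair was chosen for showing the pattern. Preferential export of let-7b, reads shared between these near-identical paralogs, and loss of let-7a during vesicle preparation therefore stay open.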
